A study of Arabidopsis thaliana with 2 samples.

How the data were processed

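The series holds 1 mRNA library of wild-type and 1 of hy5-215 whole seedlings. Per the labels' protocols, total RNA was treated with DNase, polyadenylated RNA was selected with oligo(dT) beads, cDNA was primed with random hexamers, and the double-stranded cDNA was fragmented by nebulization before Illumina library construction, which marks no strand. The submitters' processing notes name Bowtie, and the series design says that uniquely mapped reads were kept. Its version and settings and the genome build are not given in the sources used here.

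The deposited files list aligned reads, per the file headers with chromosome, strand, start, end and sequence, and hold no gene counts from the authors. They held 2443191 lines for wild type (1218472 of 41 bases and 1224719 of 42 bases) and 2034831 for hy5-215 (998806 and 1036025). No line was repeated in either file, so identical reads appear to have been merged before deposit, and a line can stand for more than 1 read. All lines lay on the nuclear chromosomes, and organelle reads were not analysed here. The deposited coordinates ran past the ends of chromosomes 1, 2, 3 and 5 of the reference used here, TAIR10.1, and belong to another build. No coordinate was converted. The read sequences were instead matched to TAIR10.1 with BWA 0.7.19 without gaps, with up to 5 mismatches and up to 2 in the first 28 bases. A single best place was found for 2416795 wild-type reads (98.9%) and 2012146 hy5-215 reads (98.9%), and the start equalled the deposited one for 2.86% and 3.17%. Of these reads 67.2% and 76.7% had no mismatch. Lines with an unread base made up 6.03% and 2.69%.

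Reads were assigned by their midpoint to merged exons of the RefSeq annotation of TAIR10.1, on either strand, and the 3.91% and 3.34% of reads in exons of more than 1 gene were left out. Without strand, a gene and an antisense partner cannot be told apart. Reads were scaled to each library's total in nuclear protein-coding exons. Genes with at least 20 reads over both libraries were compared. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, which covers counting error only and compares the libraries, not the genotypes. A gene was called where the whole interval lay beyond 1.5-fold. Log2 ratios have 0.5 read added to each count. Where 1 library had 0 reads, the fold is a bound against a floor of 3 reads in that library. Shares have exact binomial 95% intervals.

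The 23 gene lists hold 333 loci, all present in the annotation by locus code, and were fixed before the data were examined, as were the calling rule, the scaling and most of the other settings. A list's median log2 ratio, given for 22 lists with at least 3 measured members, was placed among 10000 random lists of the same size drawn from bins of 200 genes of similar mean expression. A list is described as outside its random lists below percentile 2.5 or above percentile 97.5. Genes were named by a rule fixed at the same time: HY5, the 12 highest and 12 lowest protein-coding genes by the interval bound nearest 1, up to 4 called members of each list with the farthest bounds (the 2 with most reads where none was called), HYH, COP1, CHS, CCA1, BBX21, BBX22 and BBX24, and MIR genes past 20 reads. For named and listed genes other than MIR genes, the share of 41-base exon windows, taken every 3 bases, with a single place in the genome at up to 2 mismatches was computed, and counts of genes under 80% are called uncertain.

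The other settings were other scalings, read minimums, thresholds, intervals, features, read subsets and random lists. Added after seeing the data were an adjustment of log2 ratios by least squares on spliced length, exon number, GC content and purine share (linear and squared terms, fitted on genes with 200 reads or more), random lists matched on length, purine share and level, subsets by read length, competition among coding genes only, and 2 treatments of merged reads. The adjustment was settled on after other regressions had been looked at, and expression level was left out of it. Base differences were positions with 5 or more reads in both libraries.

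The steps were tested on simulated data for hy5-215 against wild type with 15799 genes, of which 200 were changed. Counts were drawn as independent Poisson values, without merged reads, added variance between libraries or, unless stated, a trend. Error rates in the real libraries can therefore be higher. Among changed genes with 20 reads or more, 43.8% of those with a 2-fold change and 95.7% of those with a 4-fold change were called, against 77.4% and 39 of 39 with 200 reads or more. Of 15599 unchanged genes 2 were called. With a simulated trend, the slope of the fitted on the true trend was 1.01, and calls among unchanged genes fell from 1674 to 5 on adjustment. That trend was linear in length and purine share, which are terms of the adjustment itself. Its recovery therefore does not show how well the adjustment removes the trend of the real libraries. Random lists of 12 unchanged genes lay outside the random range in 8 of 200 draws. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.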

Results

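Messenger RNA was sequenced from whole seedlings of Arabidopsis thaliana, accession Columbia (Col-0), of the wild type and of hy5-215, a mutant of HY5 (ELONGATED HYPOCOTYL 5), a bZIP transcription factor that promotes light-dependent seedling development. Per the labels, seeds spent 4 days at 4°C and seedlings then grew under constant white light at 22°C for 6 days. Each genotype had 1 library, so no difference below has a replicate check, no p-value across genes is given, and intervals cover counting error between these 2 libraries only. The deposited files held 2443191 lines for wild type and 2034831 for hy5-215, and 2266147 and 1890335 of these fell in exons of nuclear protein-coding genes. No line is repeated in either file, so identical reads appear to have been merged, which would compress counts in abundant genes. Ratios are hy5-215 over wild type, with reads scaled to each library's total in coding exons, given, with exact 95% intervals in brackets. A gene is called higher or lower where the whole interval lies beyond 1.5-fold. The comparison asks which transcripts differ in level between seedlings with and without functional HY5.

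HY5 itself (AT5G11260, chromosome 5, 3593335 to 3595073 in TAIR10.1, 4 exons) was read in both libraries, with 39 wild-type reads and 24 hy5-215 reads in exons. Its ratio was 0.738 [0.424 to 1.26], so no difference in transcript level was detectable at this depth. Exon 3 held 15 wild-type and 4 hy5-215 reads, and exon 1 held 11 in each library. The level checks little here, because hy5-215 is a point allele and its transcript need not be absent. Only 1 base of the gene was covered by 5 or more reads in both libraries, so the gene was too thinly read to check the allele's own base by that rule. Base differences elsewhere separated the libraries. Over 2903360 bases covered by 5 or more reads in both, 10 positions had 1 base in every wild-type read, equal to the reference, and another base in every hy5-215 read, and all 10 were G-to-A or C-to-T changes. Of these changes 6 lay on chromosome 5 between positions 307829 and 5586989, an interval that includes HY5. The nearest on either side of the gene were C3403937T in AT5G10770 (5 wild-type and 7 hy5-215 reads) and C3671356T in AT5G11480 (5 and 6 reads), written as reference base, TAIR10.1 position on the reference strand and hy5-215 base. Where only 80% of each library's reads had to agree, 21 positions differed in hy5-215 alone and 6 in wild type alone.

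**Figure D1:**
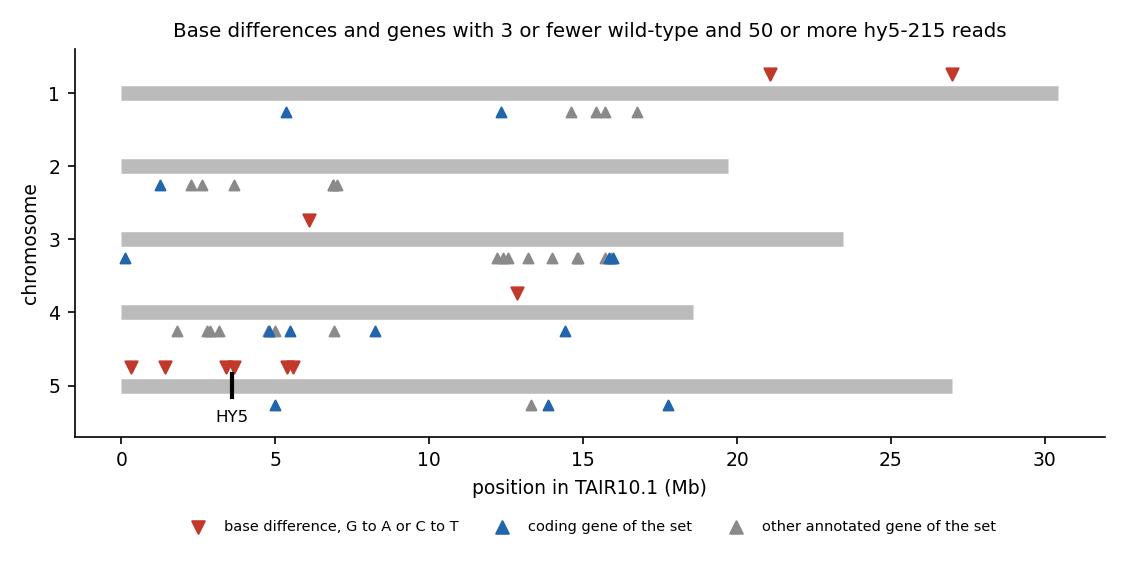
Chromosomes 1 to 5 drawn to scale in TAIR10.1 coordinates (Mb). Triangles above a chromosome mark the 10 base differences with the reference base in every wild-type read and 1 other base in every hy5-215 read, 6 of them around HY5 (black bar); triangles below mark the 40 annotated genes with 3 or fewer wild-type and 50 or more hy5-215 reads, 13 of them protein-coding.

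Across the genome, 2225 genes were higher and 697 lower in the hy5-215 library among 15799 protein-coding genes with at least 20 reads, and 12877 were called neither. The median gene lay at a log2 ratio of 0.19. Scaling the libraries by that median gave 1591 higher and 1239 lower genes, or 56.2% higher among the calls against 76.1%, while a trimmed mean of ratios gave 1628 and 1203 and the upper quartile 1647 and 1176. Genes with long or purine-rich exons had higher ratios. Across the 5103 genes with 200 reads or more, which are not independent replicates, Spearman's rho of the log2 ratio was 0.56 with spliced exon length, 0.54 with exon number and 0.43 with purine share. Median exon length was 2868 bases in the genes called higher, 1159 bases in those called lower and 1759 bases in the rest. Length, exon number, GC content and purine share together accounted for 53.9% of the variance of these log2 ratios. With ratios adjusted for these 4 properties, a step chosen after seeing the data, 790 genes were higher and 256 lower, of which 624 and 170 were called the same way without adjustment. The adjusted ratios were not rescaled, and their median still lay at a log2 ratio of 0.17. The 75.5% higher among the adjusted calls thus depends on the scaling too. All 2225 and 697 calls had the same sign in the 41-base and the 42-base reads taken separately. The genes were called on the sum of these same reads, so that agreement was nearly fixed in advance. Taken alone, the 41-base reads called 1313 genes higher and 438 lower, and the 42-base reads 1550 and 460, with fewer genes compared. This is a technical check only.

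**Figure D2:**
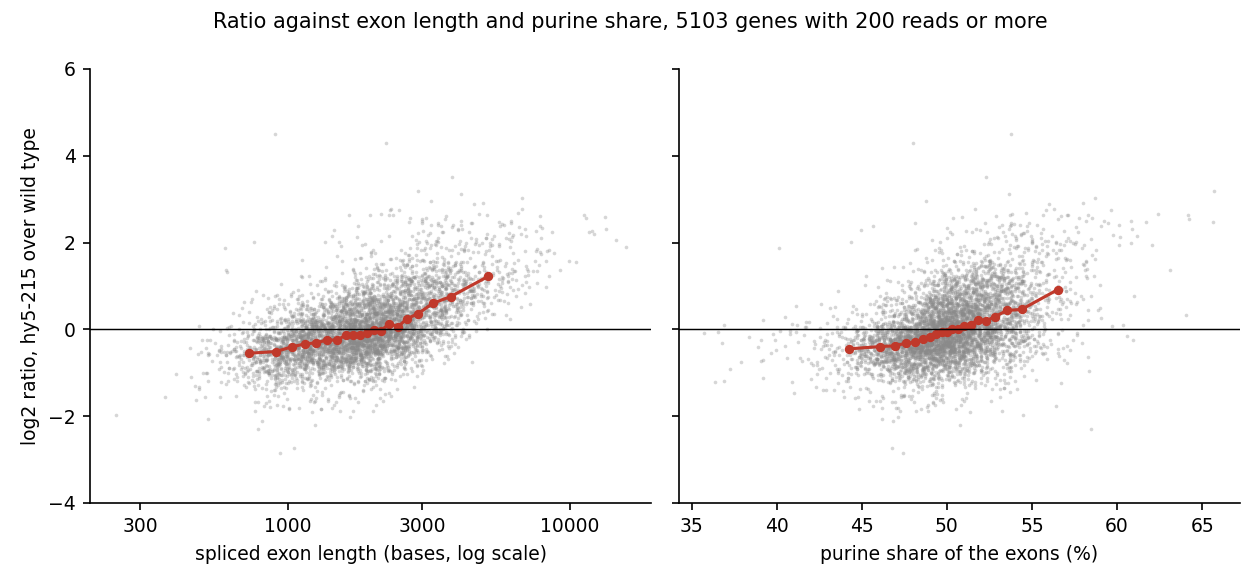
Log2 ratio of hy5-215 over wild type (y axis) against spliced exon length in bases (left, log scale) and purine share of the exons in percent (right) for the 5103 genes with 200 reads or more. Grey points are genes and red points are medians of 20 classes of equal size, which rise with both properties.

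Of the 12 protein-coding genes farthest above the wild-type level by their intervals, 7 had no wild-type read. AT3G01345 (chromosome 3, 129138 to 130749), annotated as an uncharacterized protein, had 1 wild-type and 454 hy5-215 reads, a ratio of 544 [97.2 to 21540]. AT2G03965 (chromosome 2, 1251510 to 1252989), also uncharacterized, had 1 and 285 reads. With 0 wild-type reads and a floor of 3 reads for that library, AT4G08593 was at least 30.4-fold higher, CRA1 at least 28-fold, AT4G07965 at least 26.0-fold, AT5G35660 at least 22.0-fold, and the glycosyl hydrolase genes AT3G44070 and AT3G44265 at least 24.4-fold each. AT4G29200, annotated as related to beta-galactosidases, was at least 20.8-fold higher. The exact intervals of these 7 ratios reach lower than the floor, starting at 24.1 for AT4G08593 and at 16.3 for AT4G29200. After adjustment for gene properties the interval of AT5G35660, whose exons are 70.4% purine, started at only 3.54, while that of AT4G08593 started at 37.0. Only 71.4% of the 41-base windows of AT3G44265 are unique in the genome, so its count is uncertain. The other 3 of the 12 highest were the cell wall-associated kinase WAK1, with 8 and 174 reads and a ratio of 26.1 [12.9 to 61.4], the pathogenesis-related gene PR1 with a ratio of 23.6 [12.6 to 50], and the transporter ABCG40 with a ratio of 43.8 [11.7 to 368]. WAK1 has related copies, with 79.2% of its windows unique. After adjustment ABCG40 had a lower ratio of 21.1 [5.63 to 177.5] and PR1 a higher one of 32.3 [17.2 to 68.4], and all 12 genes kept their call.

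At the other end, the lowest gene by its interval among those annotated as protein-coding was IPS1 (chromosome 3, 3050989 to 3051530), a phosphate starvation-induced transcript. IPS1 had 113 wild-type and 7 hy5-215 reads, a ratio of 0.0743 [0.0292 to 0.158]. After adjustment for gene properties its ratio was 0.1675 [0.06585 to 0.3566], above that of GRP9 at 0.153 [0.134 to 0.174]. Its rank thus held only without adjustment, while all 12 lowest genes kept their call. AT5G03545, annotated as expressed in response to phosphate starvation, had 945 and 108 reads and a ratio of 0.137 [0.111 to 0.167], and AT5G20790 a ratio of 0.217 [0.175 to 0.267]. MYB12, an activator of flavonol genes, had 23 reads in wild type and 0 in hy5-215 and was at least 6.39-fold lower against the same floor, with an interval that ends at a ratio of 0.209. The alcohol dehydrogenase gene ADH1 had a ratio of 0.171 [0.107 to 0.264] and AT4G33070, a pyruvate decarboxylase gene, 0.121 [0.0537 to 0.241]. GRP9, a glycine-rich protein gene, had 1637 and 276 reads, a ratio of 0.202 [0.177 to 0.230], with 79.9% of its windows unique. The rest of the 12 lowest were AT1G19200 at 0.0931, AT2G09990 at 0.104, AT1G47400 at 0.114, AT3G43110 at 0.142 and AT4G20390 at 0.147. Only 62.2% of the windows of AT2G09990 are unique, so its count is uncertain.

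**Figure D3:**
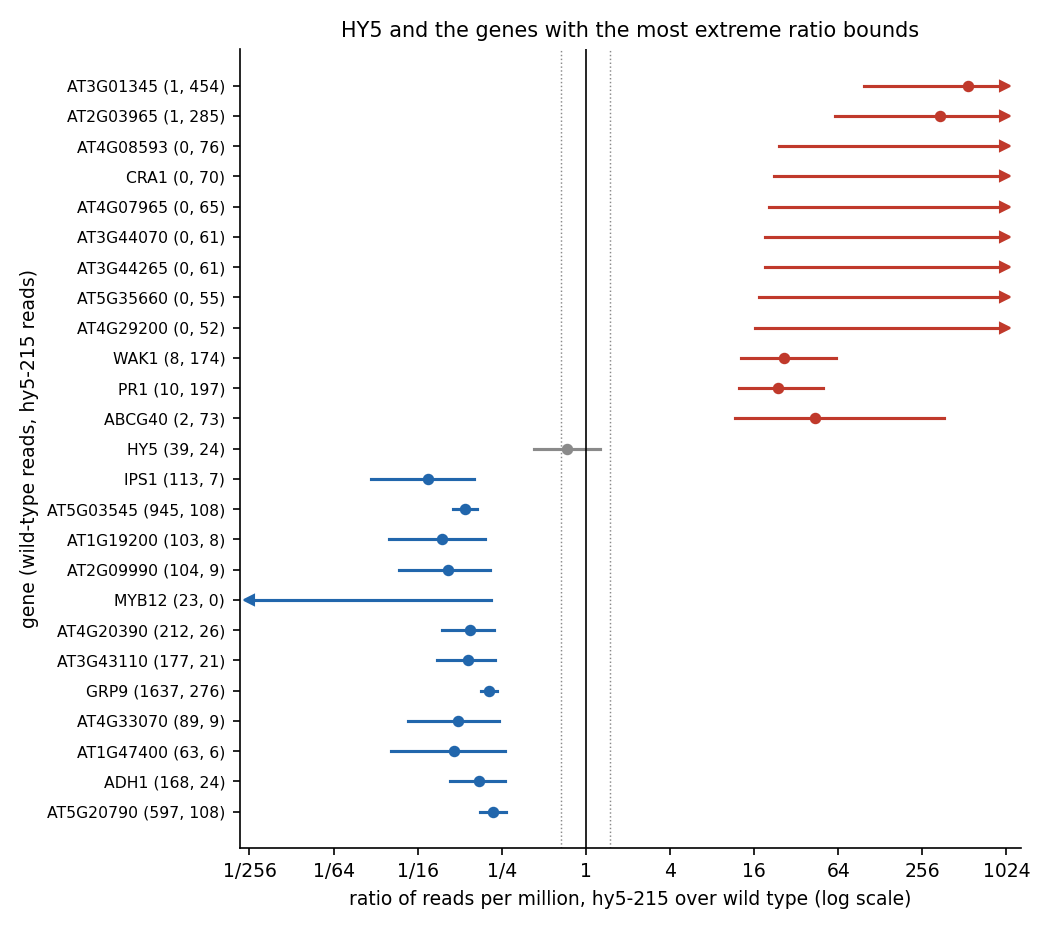
Ratio of scaled reads, hy5-215 over wild type (log scale), for HY5 and the 12 highest and 12 lowest protein-coding genes, with wild-type and hy5-215 reads in parentheses. Points are ratios, bars are exact 95% counting intervals, arrowheads mark bars that leave the axis, and dotted lines mark 1.5-fold; HY5 spans 1 at 0.738.

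Early flavonoid genes were low in the hy5-215 library. Of the 10 measured, 5 were lower and none higher, and the list's median log2 ratio of -1.18 lay below all 10000 random lists of the same size matched on mean expression. Chalcone synthase (CHS, listed as TT4), the entry enzyme of the pathway, had 367 and 82 reads and a ratio of 0.268 [0.208 to 0.341]. Flavonol synthase FLS1 had a ratio of 0.245 [0.141 to 0.404] and the glycosyltransferase UGT78D2 0.458 [0.339 to 0.613]. After adjustment for gene properties 3 genes, CHS, FLS1 and MYB12, remained called and UGT78D2 did not, with a median of -1.08 that again lay below every random list. UV-B and photoprotection genes were low as well, with 3 of 7 measured genes lower, none higher and a median of -1.14 at percentile 0.005. RUP1 and RUP2, repressors of the UV-B photoreceptor, had ratios of 0.143 [0.0691 to 0.269] and 0.293 [0.192 to 0.434], and the early light-induced gene ELIP1 had 35 and 4 reads, a ratio of 0.137 [0.0354 to 0.383]. Adjustment called 4 of the 7 lower and left the median at -1.30. Late anthocyanin genes were largely too rare to compare, with 4 of 16 measured and none called. Their median was -0.02, percentile 39.4, and MYBL2 and TTG1 had ratios of 0.859 [0.683 to 1.08] and 0.893 [0.692 to 1.15]. None of the 7 general phenylpropanoid genes was called (median -0.15, percentile 36.3), PAL1 having a ratio of 0.807 [0.713 to 0.914] and C4H 0.723 [0.632 to 0.826].

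Photoreceptor and light signalling genes were high in the hy5-215 library, with 12 of 27 measured genes higher, none lower and a median of 0.98 above all 10000 random lists. COP1, the ubiquitin ligase that targets HY5 for degradation, had 37 and 121 reads and a ratio of 3.92 [2.69 to 5.83]. Phytochrome gene PHYE had a ratio of 3.47 [2.39 to 5.14], PIF1 (listed as PIL5), a bHLH repressor of light responses, 3.6 [2.32 to 5.73], and the COP1 partner SPA3 2.87 [2.1 to 3.95]. Adjustment lowered the median to 0.39, percentile 99.3, and the number of genes called from 12 to 4. COP1 and SPA3 were no longer called, because their ratios of 2.1 [1.44 to 3.12] and 1.96 [1.44 to 2.71] reached below 1.5-fold. Against random lists matched on length, purine share and level, the adjusted median was at percentile 96.4, inside the middle 95% of random lists. HYH, the closest relative of HY5, had 56 and 34 reads, a ratio of 0.728 [0.461 to 1.13]. Among 10 B-box genes 1 was lower, BBX28 at 0.465 [0.380 to 0.566], and the median of -0.34 stood at percentile 3.13. BBX21, BBX22 and BBX24, of the same list, had ratios of 0.711 [0.599 to 0.842], 0.738 [0.485 to 1.11] and 0.655 [0.550 to 0.777], none of them called. After adjustment these 3 ratios were 0.978, 0.834 and 0.941, and that of HYH was 0.979. The adjusted B-box median was -0.06 at percentile 13.6, and BBX28 kept its call at 0.466.

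Clock genes included 4 of 15 that were higher and none that were lower, with a median of 0.59 at percentile 96.0. PRR7 and PRR3, pseudo-response regulators, had ratios of 6.07 [4.13 to 9.17] and 7.06 [3.45 to 16.3], ELF3 of the evening complex 2.76 [2.1 to 3.66], and the morning gene CCA1 2.19 [1.69 to 2.83]. CCA1 lost its call on adjustment, at 1.59 [1.23 to 2.06]. The others kept it at lower ratios of 3.33 for PRR7, 4.95 for PRR3 and 2.25 for ELF3. Light-harvesting and Rubisco small subunit genes were low, with 9 of 20 lower, none higher and a median of -0.61 at percentile 0.31. The chlorophyll a/b-binding genes CAB3, CAB2 and CAB1 had ratios of 0.266 [0.241 to 0.293], 0.279 [0.257 to 0.302] and 0.349 [0.331 to 0.368], but 54.4%, 57.2% and 46.1% of their windows are unique and their counts are uncertain. LHCB3 had a ratio of 0.527 [0.501 to 0.554]. These are short, abundant transcripts, and CAB1 held 6252 wild-type and 1819 hy5-215 reads on 1230 bases of exon. If identical reads were merged, such counts can be distorted, which the narrow intervals do not cover. The list median moved to -0.16, percentile 51.9, with identical positions counted once and to -0.195, percentile 57.3, with reads without mismatch. After adjustment it was -0.11, percentile 78.3, and 2 genes were called. Of 18 chlorophyll synthesis genes 1 was higher and 1 lower (median -0.01, percentile 92.6). CHLD (listed as ALB1), a magnesium chelatase subunit, had a ratio of 2.06 [1.82 to 2.33], and GUN4, a chelatase regulator, 0.133 [0.0150 to 0.556] on 18 and 2 reads. After adjustment CHLD had a ratio of 1.19 [1.06 to 1.35] and GUN4 0.224 [0.0252 to 0.937], and neither was called.

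**Figure D4:**
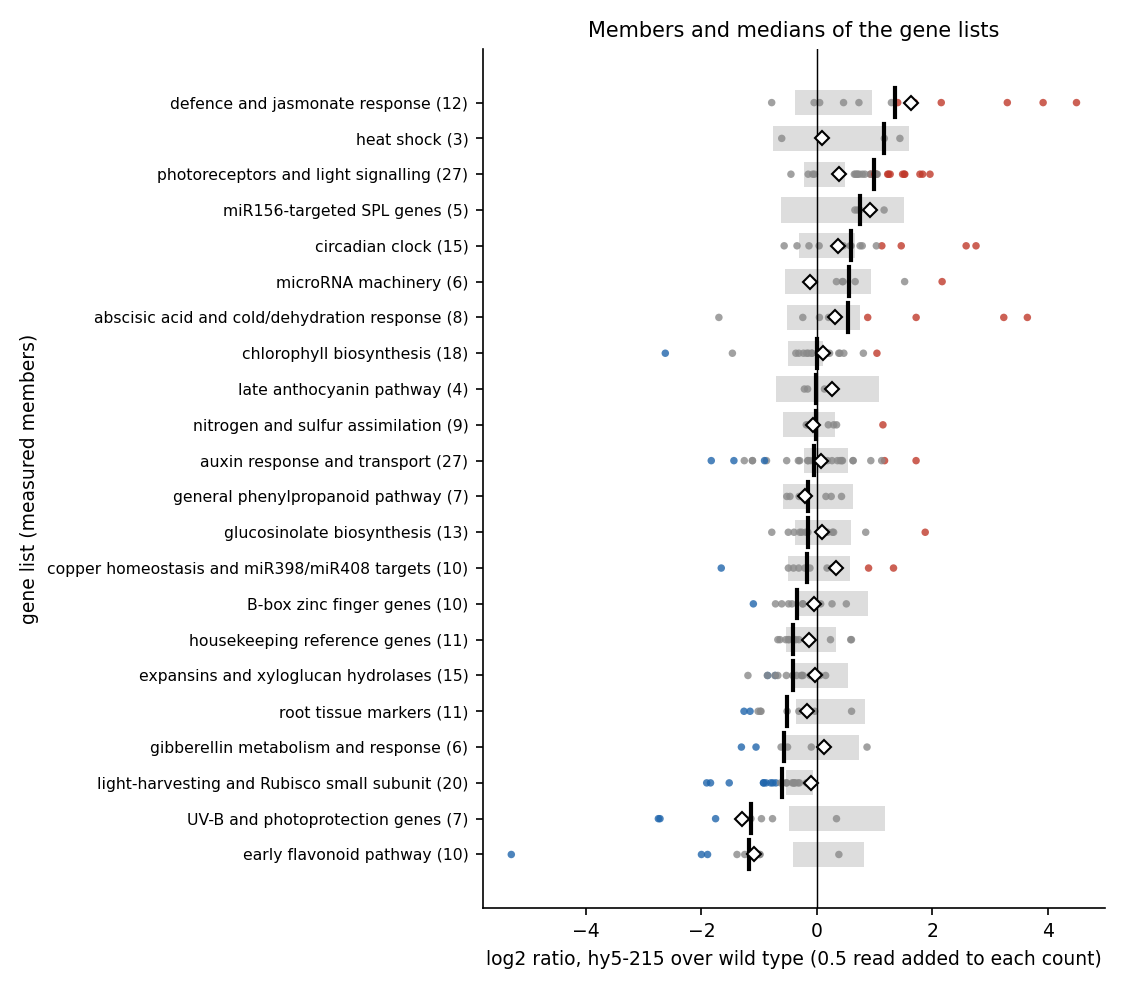
Log2 ratio of hy5-215 over wild type for the measured members of 22 gene lists fixed before the data were examined (points; red called higher, blue called lower, grey neither). Black bars are list medians and open diamonds medians after adjustment for gene properties. Grey bands are the middle 95% of 10000 random lists of unadjusted ratios matched on expression, so they apply to the bars and not to the diamonds. Early flavonoid and UV-B medians lie to the left of their bands, the defence median to the right. After adjustment these 3 medians also lay outside random lists of adjusted ratios, at percentiles 0, 0 and 100.

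Defence and jasmonate genes were high, with 6 of 12 higher, none lower and a median of 1.34 at percentile 99.93, and 1.63 above all random lists after adjustment. Besides PR1, the transcription factor WRKY70 had 7 and 94 reads and a ratio of 16.1 [7.51 to 41.1], the camalexin enzyme PAD3 12 [2.91 to 106], and PR2 (listed as BGL2) 4.56 [2.55 to 8.66]. Of 8 genes of abscisic acid and cold or dehydration response 4 were higher (median 0.54, percentile 92.2). RD29B (listed as LTI65) had a ratio of 14.4 [4.55 to 73.0] on 3 and 36 reads, COR15A 10.8 [3.32 to 55.6] on 3 and 27 reads, RD29A (listed as LTI78) 3.3 [2.76 to 3.96] and ERD10 1.84 [1.53 to 2.22], and only COR15A kept its call after adjustment. RD29B lost it at an adjusted ratio of 4.57 [1.45 to 23.2], whose interval reaches just below 1.5-fold. Auxin genes went both ways, with 2 higher and 3 lower of 27 (median -0.05, percentile 20.1). The early auxin-response genes IAA1 and IAA2 had ratios of 3.36 [1.82 to 6.52] and 2.26 [1.78 to 2.87], and IAA17 (listed as AXR3), a repressor of auxin response, 0.368 [0.297 to 0.453]. These 3 kept their calls after adjustment and SAUR21, at 0.27 [0.115 to 0.565], did not. Only 77.5% of the windows of SAUR21 are unique, so its count is uncertain. Of 6 measured gibberellin genes 2 were lower (median -0.56, percentile 3.2), GASA1 at 0.403 [0.352 to 0.462] and GASA6 at 0.481 [0.422 to 0.548]. Among 15 expansin and xyloglucan hydrolase genes 2 were lower, EXPA1 at 0.553 [0.506 to 0.604] and XTH4 at 0.607 [0.561 to 0.657], with a median of -0.42 at percentile 2.14. After adjustment no gene of these 2 lists was called, and the medians were 0.12 at percentile 64.9 for the gibberellin list and -0.04 at percentile 31.2 for the expansin list, both inside the middle 95% of random lists.

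The other metabolic and regulatory lists lay within the middle 95% of their random lists. Of 9 nitrogen and sulfur assimilation genes 1 was higher (median -0.02, percentile 81.2), the sulfate transporter SULTR1;2 at 2.21 [1.73 to 2.84], which lost its call on adjustment at 1.59 [1.24 to 2.04]. Of 10 genes of copper homeostasis and of miR398 or miR408 targets 2 were higher and 1 lower (median -0.17, percentile 29.6). The copper-response regulator SPL7 had a ratio of 2.52 [1.78 to 3.62], the superoxide dismutase chaperone CCS 1.86 [1.52 to 2.28], and the copper transporter COPT1 0.316 [0.258 to 0.386]. CCS alone of these kept its call after adjustment. None of 5 measured SPL genes targeted by miR156 was called (median 0.75, percentile 72.3), SPL2 having a ratio of 2.26 [1.38 to 3.79] and SPL10 1.64 [0.874 to 3.14]. Of 6 microRNA machinery genes 1 was higher (median 0.56, percentile 85.9), DCL1, the enzyme that processes microRNA precursors, at 4.53 [3.29 to 6.34]. This long transcript had an adjusted ratio of 1.32 [0.961 to 1.85]. Of 13 glucosinolate genes 1 was higher (median -0.16, percentile 18.3), the regulator MYB29 at 3.75 [2.1 to 7.05]. None of the 3 measured heat shock genes was called (median 1.17, percentile 91.9), with ratios of 0.653 [0.470 to 0.900] for HSP70 and 2.26 [1.39 to 3.76] for HSP101.

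Markers of tissue composition also differed between the libraries. Root markers had a median of -0.52 at percentile 0.600, with 2 of 11 lower and none higher. The iron transporter IRT1 of the root epidermis had a ratio of 0.446 [0.321 to 0.611] and the root-hair expansin EXPA18 0.413 [0.267 to 0.622]. Their median after adjustment was -0.17, percentile 4.26, with none called. Of 11 seed storage and oil body genes only the storage proteins CRA1 and CRC (listed as CRU3) passed 20 reads, so no median is given. CRA1 had 0 and 70 reads, and CRC had 0 and 31 and was at least 12.4-fold higher. None of 11 housekeeping reference genes was called, and their median was -0.41 at percentile 9.54. EF1A (AT5G60390) had a ratio of 0.625 [0.577 to 0.677], with 78.0% of its windows unique, and ACT2 0.642 [0.589 to 0.698].

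Annotated MIR genes were rarely read, and reads of a primary transcript outside the annotated gene were not counted for it. Of 326 annotated MIR genes 50 had a read, with 163 reads in wild type and 56 in hy5-215 altogether. Only MIR414 (chromosome 1, 25137456 to 25137563) passed 20 reads, with 62 and 15 reads and a ratio of 0.290 [0.153 to 0.516], and 0.661 [0.349 to 1.18] after adjustment. Exons held 98.9% of wild-type reads and 98.7% of hy5-215 reads. Introns held 0.727% [0.717 to 0.738] and 0.994% [0.980 to 1.01], and intergenic sequence 0.330% [0.323 to 0.338] and 0.349% [0.341 to 0.358]. Reads on the sense strand of the annotated gene made up 49.4% of coding reads in wild type and 58.7% in hy5-215, although the protocol in the labels marks no strand. Chloroplast and mitochondrial transcripts were not analysed here.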

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

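The adjustment for gene properties, random lists matched on those properties, the read length subsets, reads with 2 or more mismatches, the occupancy correction and competition among coding genes were chosen after seeing the data; the other settings were planned. Each genotype had 1 library, so no replicate could be left out. No paired analysis was possible because each genotype had 1 library. Organelle reads, named in the planned scaling by all alignments, were not analysed here. HY5 was called in none of the 20 settings that gave it a value; a minimum of 100 reads and reads with 2 or more mismatches gave it none. The count of higher genes, 2225, was 1333 at a minimum of 100 reads, 1067 beyond 2-fold, 5164 with the interval excluding 1, 1142 with a wider interval, 1410 with identical positions counted once, 1431 with sense reads only, 790 after adjustment, 1313 with 41-base reads and 220 with reads of 2 or more mismatches. The count of lower genes, 697, was 1239, 1203 and 1176 under the median, trimmed mean and upper quartile scalings, 168 beyond 2-fold, 3066 with the interval excluding 1, 303 with a wider interval, 256 after adjustment, 438 with 41-base reads, 460 with 42-base reads and 142 with reads of 2 or more mismatches. Fewer genes could be compared with a minimum of 100 reads (8817), 41-base reads (13360), 42-base reads (13369), sense reads (13757) and reads with 2 or more mismatches (3430). Depth limits the calls, since 2-fold changes were called in 43.8% of simulated changed genes with 20 reads or more.

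Of the list medians under other settings, 496 kept their place inside or outside the middle 95% of random lists, 13 moved inside, 24 moved outside and 4 moved past the middle of their random lists. Early flavonoid, UV-B and defence lists kept their place in every setting that gave them a value. The light-harvesting median (-0.61) moved past the middle at -0.16 with identical positions counted once, -0.20 with reads without mismatch and -0.11 after adjustment, and moved inside at -0.205 with the occupancy correction and at -0.108 with random lists matched on gene properties. Root markers (-0.52) moved past the middle at 0.65 with reads of 2 or more mismatches and moved inside at -0.36 with a minimum of 100 reads and at -0.17 after adjustment, with either matching. Light signalling moved inside at 0.70 with reads of 2 or more mismatches and 0.39 with matching on gene properties. Expansins moved inside at -0.39 with a minimum of 1 read, -0.40 with wild type thinned, -0.42 with competition among coding genes, -0.44 with reads of 2 or more mismatches and -0.035 after adjustment, with either matching. These lists moved outside: B-box genes at -0.43 (minimum of 1 read), -0.44 (whole gene span), -0.38 (wild type thinned), -0.54 (42-base reads) and -0.30 (mean); chlorophyll synthesis at 0.12 (minimum of 100 reads), 0.14 (sense reads) and 0.11 (41-base reads); gibberellin at -0.84 (minimum of 100 reads), -0.82 and -0.86 (41-base and 42-base reads), -1.28 (2 or more mismatches) and -0.56 (unmatched lists); abscisic acid at 0.88 (minimum of 1 read), 0.72 (positions once), 0.86 (no mismatch), 0.76 (occupancy) and 0.97 (mean); clock at 0.55 (positions once), 0.72 (sense reads), 0.74 (42-base reads), 0.58 (occupancy) and 0.77 (mean); housekeeping at -0.41 (unmatched lists). The cause was not tested for any of these. For single named genes, 1569 values kept their call or lack of one, 133 lost a call and 18 gained one. None (0) changed direction with a call in either setting, and 2 shares moved. Genes without a call could cross a ratio of 1 and still count as unchanged, as MYBL2 did on adjustment, from a log2 ratio of -0.22 to 0.38.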

Other observations

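The gene sets and patterns in this part were chosen after seeing the data; the tests of transcript ends, root tissue, shared copies and general silencing were written in their present form after related values had been seen, and the other 3 before. Phosphate-starvation genes, a list of 27 drawn up after 5 of them had stood out, were low in the hy5-215 library beyond those 5. Of 18 others measured, 9 were lower and 1 higher, with a median log2 ratio of -1.22. SPX3, a phosphate sensor, had 38 and 4 reads and a ratio of 0.126 [0.0327 to 0.351], the galactolipid synthase MGD2 0.170 [0.0938 to 0.288], the sulfolipid synthase SQD2 0.362 [0.287 to 0.453], and the phosphatase PS2 0.354 [0.212 to 0.569]. The phosphate exporter PHO1 was the exception, at 2.14 [1.67 to 2.74], and lost its call on adjustment at 1.47 [1.15 to 1.89]. Among the prompting genes the acid phosphatase PAP17 had a ratio of 0.247 [0.196 to 0.308] and the transporter PHT1;4 0.271 [0.203 to 0.357].

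For this phosphate pattern, the length and sequence trend of the libraries was set against random lists matched on length, purine share and level. The adjusted median of the 18 genes, -1.06, was at percentile 0 of these lists, whose middle 95% ran from -0.16 to 0.45, which argues against the trend as the whole cause. A smaller share of root tissue, if it acted alike on both lists, would lower root markers as much. The adjusted phosphate median instead lay 0.89 below theirs (difference -0.888, bootstrap 95% interval -1.64 to -0.0745). Before adjustment the medians were -1.22 for the phosphate genes and -0.52 for the root markers. The interval resamples genes, not seedlings, so a part played by root tissue is not excluded. The genotype, a part played by root tissue, and any difference in growth medium or handling between the 2 samples stay open. They cannot be separated with 1 library each.

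A second group, widened to all gene classes after its coding members had been seen, was read almost only in the hy5-215 library. There, 40 annotated genes had 50 or more reads against 3 or fewer in wild type, and 1 gene, the noncoding AT2G08825, had the reverse with 69 and 2 reads. Of the 40, 25 are pseudogenes in the annotation, a class that here includes transposon genes, 13 are protein-coding and 2 are noncoding RNAs. The pseudogene AT3G44215 had 0 and 328 reads and was at least 131-fold higher, and the neighbours AT2G15810 and AT2G15800 had 0 and 229 and 0 and 131. Reads shared between gene copies stay open as an account of which copy was read, with a median of 86.2% unique windows (bootstrap 95% interval 71.4 to 98.2) and a lowest value of 23.4%. For the 13 coding genes the median was 100%.

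For these 40 genes a general loss of silencing in the hy5-215 sample was tested on the pseudogene classes without the 25 of the group, which held 6215 wild-type and 9067 hy5-215 reads over 4818 genes. The ratio of 1.75 [1.69 to 1.81], or 2.28 with the 25 included, lay between the 1.5-fold and 3-fold bounds set for it and leaves that question open. A loss of DNA methylation was tested on FWA, SDC, QQS and the transposon gene AtMu1, which are known to be silenced by methylation or to vary with it. None of the 4 had a ratio interval above 1.5-fold (0 of 4 genes). FWA had 0 and 1 reads, SDC and AtMu1 none in either library, and QQS 27 and 20, so methylation loss at these 4 genes is not seen, while other loci were not examined. Silencing lost at a subset of loci in this seed stock or RNA from another plant line in the sample may account for the group, and neither can be told apart from an effect of hy5-215 with 1 library.

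The rise of the ratio with exon length and purine share was examined within genes. If the libraries had differed in a preference for purine-rich sequence, windows of 100 bases inside a gene would show it, but the within-gene slope was -0.03 log2 units per 10 percentage points (-0.0292, bootstrap 95% interval -0.0373 to -0.0209, 4133 genes) against 0.88 between genes, which argues against such a preference. Loss of reads within 200 bases of transcript ends was tested in 2216 genes of 2000 bases or more. There, Spearman's rho of the ratio with length was 0.508 [0.475 to 0.539] from reads over 200 bases from both ends, and 0.508 from all reads. In these genes the trend with length thus did not rest on reads near the ends. The 200 bases at each end are a small part of genes this long, so the test could hardly have changed the correlation. It does not show whether such loss occurred, and loss over longer stretches or in shorter genes was not tested. A difference in RNA quality or in shearing of cDNA between the libraries stays open, as does a biological difference between the genotypes. The merging of identical reads was not tested as a cause and stays open too, in libraries where 67.2% and 76.7% of reads had no mismatch. With identical positions counted once, the median log2 ratio was 0.02 instead of 0.19, and 1410 genes were higher instead of 2225.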
